A study of Mus musculus with 15 samples.

How the data were processed

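Gene expression was measured on 15 Affymetrix mouse expression arrays, each hybridised with biotin-labelled RNA amplified from 500 ng of total RNA at day 4, from T helper cell cultures or, in 3 arrays, from samples labelled APC alone. The deposited table held log2 expression values for 45101 probe sets, made by the authors with RMA, a method that corrects background, normalizes quantiles and summarises probes, per the submitters' processing notes. The software version is not given in the sources used here, and the log base was taken from the range of the values. The values were used as deposited. The precision of every comparison was limited by the number of arrays, 2 per activated group and 1 per group of APC alone.

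Probe sets were named from the platform annotation of 2016. Of the 45101 probe sets, 34958 were paired with 1 gene symbol, 932 with several and 9211 were unnamed here. Only probe sets with 1 symbol were used, and each of the 18194 genes was represented by its probe set with the highest mean over all arrays. A gene was tested if that probe set exceeded the 40th percentile of the table (5.07 on the log2 scale) in at least 2 arrays, which left 15498 genes. No detection calls were used here, so a signal below that threshold is not told from background. Of 250 called differences of named genes, 78 had a group mean below it, and for these the size and rank are uncertain and no fold is given. Of 155 named genes with several probe sets, 2 had another probe set that moved the opposite way in the averaged activation contrast at an unadjusted p under 0.05 for both. They were Il2ra, at 0.97 with the probe set used and -1.18 with the other, and Pdk1, at -0.37 and 0.93.

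Samples were grouped by the culture, activation and replicate number in the labels. A limma model (version 3.58.1, R 4.3.3) with 1 mean per group was fitted to all 15 arrays, so that the groups shared an estimate of the spread with 6 residual and 4.38 prior degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 are referred to as called. Contrasts were PBAB minus HA in each of the 3 cultures and averaged over them, the differences of these differences with an F test for the interaction, each pair of lineages under each activation, and HA minus APC alone averaged over the cultures. The labels call the replicates biological and do not say which animals or cultures they came from, so p-values measure the spread between these samples.

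In total 35 gene lists with 589 entries, 535 of them matched to a gene on the array, were fixed before the data were examined, as were the tests of the comparisons named above, the rule for the named genes and all alternatives except 5. List tests in contrasts other than PBAB minus HA within the cultures and in the average, the test between replicate numbers, and 5 of the tests of explanations in the closing section were chosen after the data were seen. An entry of the glycolysis list, Gpi1, was matched to Pigq through a synonym, which was noticed after the results were seen, and values without Pigq stand beside that list. Each list was compared with the other tested genes by camera with an inter-gene correlation preset at 0.01, adjusted over the lists of a contrast. Beside each list stand its called members over all genes tested and adjusted over the list alone. None of the list calls in the activation contrasts held with an estimated inter-gene correlation. The named genes were the 5 largest called differences each way per activation contrast without overlap between replicates (in the average, with the same direction in all 3 lineages), up to 4 members with the smallest p of any list described, and 23 lineage genes fixed in advance, 4 of which were not tested. Lineage contrasts took the fixed genes and the 3 largest differences each way, and HA minus APC alone the 5 largest each way. The text takes the 2 members with the smallest p of each list called in an activation contrast. That last step was chosen after the values were seen. It replaced a selection among members whose calls held when an array was left out, which would have left out the only result that reversed.

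Replicate numbers were checked for pairing before the fits were compared. Over the 15 pairs of activated groups, the deviations from the group means of arrays with the same number correlated across genes at 0.309 to 0.692 (median 0.473), above 0.1 in every pair, so the numbers were taken to mark pairs. The pairing comes from the shared numbers in the labels and this check, and a fit with the number as a block was compared throughout. The main fit held no block. Every count, SE and adjusted p not said to come from a block therefore ignores the pairing.

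The fit was tested on simulated arrays. In each array a gene had the mean of the activated arrays of that lineage, plus independent noise with the spread estimated by the fit. In the simulated contrasts within Th1, Th9 and Th17 cultures, 64%, 68% and 54% of 50 genes changed 2-fold were recovered, and 94%, 98% and 92% of those changed 4-fold. In the simulated average, 94% of the genes changed 2-fold were recovered. Of 15273 unchanged genes, 12, 8, 9 and 6 were called in these contrasts, and the interaction test called 1 of 15498. A simulated shift of the cell cycle list was called in all 4 contrasts and 0 of the 34 other lists were called. The simulation held no correlation between genes and no difference between replicate numbers, and the real arrays held both. These rates therefore do not show how often the list test or the fit without a block makes false calls in the real data.

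The alternatives were no filter or a stricter one, the mean of a gene's probe sets, centring each array on its median, quantile normalization again, an intensity trend with a robust prior, array weights, both forms of the replicate block, a fit of the compared groups alone, a 2-fold minimum and leaving out each array. The 5 added after seeing the data were leaving out the 3 arrays of APC alone, a block together with an estimated correlation for the lists, the lists without Pigq, and 2 other definitions of genes abundant in APC alone. When an array was left out of a pair, the remaining array was assumed to vary like those of the other groups. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.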

Results

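The data comprised 15 arrays, 5 for each of the Th1, Th9 and Th17 lineages of helper T cells. The T cells were naive CD4 cells of 3A9 mice, which carry a transgenic receptor for hen egg lysozyme (HEL), sorted with an antibody against that receptor. In the activation called HA, HEL at 1 µg/ml (Th9) or 2 µg/ml (Th1 and Th17) was presented by irradiated (30 Gy) splenocytes acting as antigen-presenting cells (APC). In PBAB the stimulus was plate-bound anti-CD3 at 1 µg/ml and anti-CD28 at 10 µg/ml. Under both activations, Th1 cultures held IL-12 at 10 ng/ml and an antibody against IL-4 at 10 µg/ml. Th9 cultures held IL-4 at 10 ng/ml and TGF-beta at 1 ng/ml. Th17 cultures held TGF-beta at 3 ng/ml, IL-6 at 10 ng/ml and IL-1alpha at 5 ng/ml. They also held antibodies against IFN-gamma at 20 µg/ml and against IL-4 and IL-12 at 10 µg/ml each. There were 2 arrays per lineage for each activation, and 1 array per lineage labelled APC alone, whose content the labels do not define further. An array is named by culture, activation and replicate number, as in Th1 HA 2. The series asked whether antibody activation and antigen presentation yielded different T helper phenotypes. Differences are log2 values ± SE from the limma fit, with n = 2 arrays per group unless stated.

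The arrays of APC alone stood apart from the rest. They correlated with the 12 activated arrays at 0.614 to 0.727, whereas activated arrays of different lineage and activation correlated at 0.953 to 0.973 and replicates at 0.986 to 0.989. Their interquartile range was 2.02 to 2.09, against 3.02 to 3.48 in activated arrays. The 3'-minus-5' difference of the actin control, a sign of RNA quality, was 0.74 to 0.99 in APC alone, 0.05 to 0.11 in HA and 0.12 to 0.28 in PBAB. The bioB hybridisation control averaged 13.94 ± 0.24 (SD, n = 3) in APC alone, 10.17 ± 0.74 (SD, n = 6) in HA and 10.33 ± 0.73 (SD, n = 6) in PBAB. The 18S ribosomal signal averaged 8.68 ± 0.12 (SD, n = 3) in APC alone, 10.08 ± 0.69 (SD, n = 6) in HA and 10.70 ± 0.63 (SD, n = 6) in PBAB, and was higher in PBAB in 6 of 6 pairs of arrays of the same lineage and replicate number, by 0.29 to 0.77.

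Compared with APC alone, HA cultures had higher levels of all 27 cell cycle and all 15 T cell identity genes and lower levels of all 25 macrophage and monocyte genes. Birc5, which encodes the mitotic protein survivin, was higher by 6.27 ± 0.22, and Cdca5, Gbp2, Ccnb2 and Lbr by 6.19, 6.04, 6.02 and 5.93. The largest decreases were in Cd36, a scavenger receptor (-6.79 ± 0.22), Mgst1 (-5.67 ± 0.18), Apoe (-5.65 ± 0.21), 4933438K21Rik (-5.31 ± 0.20) and Lyz2, a lysozyme of macrophages (-5.27 ± 0.28; 6 arrays against 3). Of the cell cycle genes Cdk1 rose by 5.07 ± 0.18, and of the T cell identity genes Skap1 by 4.71 ± 0.11 and Cd3g by 4.54 ± 0.12. Of the macrophage genes, C1qc fell by 4.63 and Slc40a1 fell by 4.46, and 13 of 18 B cell genes fell, with 3 higher and 2 not called, for example Ms4a1 (-3.07 ± 0.14) and Fcer2a (-2.49 ± 0.13). These 4 lists had adjusted p = 2.2e-05, 0.000585, 5.13e-08 and 0.0117, and adjusted p = 0.467 with an estimated correlation for each. Of 15498 genes, 14051 were called, 7668 higher and 6383 lower in HA. The median of all genes was 0.36 higher in HA, 0.80 higher after centring each array and -0.03 after quantile normalization again, and each group of APC alone held 1 array. The HA means of Cd36, Mgst1, C1qc, Slc40a1 and Fcer2a (4.06, 4.64, 5.04, 4.80 and 4.27) and the APC-alone means of Cdca5 and Ccnb2 (4.20 and 4.88) lay below the filter threshold of 5.07. The bioB and 18S signals of APC alone did not overlap with those of HA.

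Averaged over the 3 lineages (6 arrays against 6), 13 of 17 genes of the ATF4 response, 9 of 15 targets of p53 and 10 of 23 genes of the early T cell receptor response were higher in PBAB. In turn 26 of 27 cell cycle, 18 of 25 interferon-stimulated and 17 of 25 macrophage genes were lower, and with an estimated correlation these 6 lists had adjusted p = 0.289 to 0.496. The largest increases were in Cth, an enzyme of cysteine synthesis (4.61 ± 0.31), the heat shock genes Hspa1b (4.49 ± 0.16) and Hspa1a (3.57 ± 0.20), the stress gene Nupr1 (4.28 ± 0.22) and the protease inhibitor Timp1 (4.02 ± 0.32). The largest decreases were in Lyz1, a lysozyme of phagocytes (-5.21 ± 0.29), Ifi209 (-4.95 ± 0.26), S100a6 (-4.57 ± 0.19), granzyme A, Gzma (-4.42 ± 0.53), and Slfn1 (-4.35 ± 0.16). The HA means of Cth, Hspa1b and Hspa1a (4.83, 4.69 and 3.36) and the PBAB means of Lyz1 and Ifi209 (4.07 and 4.19) lay below the filter threshold of 5.07. Of 15498 genes, 4735 were called, 2050 higher and 2685 lower in PBAB, and all had the same sign in both replicate numbers. The calls were made on the mean over these numbers, so the shared sign adds little support. In the same arrays the 3'-minus-5' difference of actin averaged 0.07 in HA and 0.21 in PBAB, with no overlap between the activations, and the 18S signal was higher in PBAB in all 6 pairs by a mean of 0.62 ± 0.17 (SD).

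Among the 27 cell cycle genes, 26 fell in the average and 1 was not called (27 fell adjusted over the list alone), for example Rrm2, a subunit of ribonucleotide reductase (-2.41 ± 0.17), and Birc5 (-2.11 ± 0.18). For cell cycle genes, camera gave adjusted p = 3.7e-14, and adjusted p = 0.305 with an estimated correlation. In the interferon-stimulated list, 18 of 25 fell, 1 rose and 6 were not called (18 and 2 adjusted over the list alone), with Xaf1 at -3.63 ± 0.26 and Ifit2 at -2.03 ± 0.15. For interferon-stimulated genes, camera gave adjusted p = 4.37e-08, and adjusted p = 0.289 with an estimated correlation. Macrophage and monocyte markers gave 17 lower, 1 higher and 7 not called of 25 (18 and 1 adjusted over the list alone), Lyz1 and Lyz2 (-3.35 ± 0.23) first. For macrophage markers, camera gave adjusted p = 4.37e-08, and adjusted p = 0.289 with an estimated correlation. B cell genes gave 1 higher, 2 lower and 15 not called of 18 (the same adjusted over the list alone). For B cells, camera gave adjusted p = 0.816 in the average, and 0.475, 0.733 and 0.393 in Th1, Th9 and Th17 cultures. Of 17 genes of the ATF4 response to amino acid shortage, 13 rose and 4 were not called (13 adjusted over the list alone), for example Atf5 (1.79 ± 0.13) and Ddit3 (2.27 ± 0.17). For ATF4 genes, camera gave adjusted p = 4.37e-08, and adjusted p = 0.299 with an estimated correlation. Of 15 targets of p53, 9 rose and 6 were not called (9 adjusted over the list alone), led by Perp (1.83 ± 0.09) and Bbc3 (1.54 ± 0.13). For p53 targets, camera gave adjusted p = 5.11e-06, and adjusted p = 0.289 with an estimated correlation.

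Genes of the early response to the T cell receptor gave 10 higher, 1 lower and 12 not called of 23 in the average (10 and 1 adjusted over the list alone), with the nuclear receptors Nr4a3 (3.37 ± 0.11) and Nr4a2 (3.05 ± 0.21) first. For early receptor response genes, camera gave adjusted p = 0.00079, and adjusted p = 0.496 with an estimated correlation. Of 12 inhibitory receptor genes, 7 rose, 2 fell and 3 were not called (7 and 2 adjusted over the list alone), with Btla at 1.27 ± 0.14 and Ctla4 at 0.91 ± 0.10. For inhibitory receptors, camera gave adjusted p = 0.0198, and adjusted p = 0.299 with an estimated correlation. Hypoxia genes gave 6 higher and 10 not called of 16 (6 adjusted over the list alone), including Ddit4 (1.39 ± 0.20) and Vegfa (1.19 ± 0.18). For hypoxia genes, camera gave adjusted p = 0.024, and adjusted p = 0.864 with an estimated correlation. The median of the hypoxia list was -0.35, 0.36 and 1.11 in Th1, Th9 and Th17 cultures, and in Th1 cultures 2 members were lower, 1 was higher and 13 were not called (adjusted p = 0.178). The averaged hypoxia call was lost without Th9 HA 2 or Th17 HA 2 (adjusted p = 0.107 and 0.159). The cytotoxic granule list gave 9 lower, 2 higher and 4 not called of 15 (9 and 2 adjusted over the list alone), Gzma and Gzmk (-1.18 ± 0.15) first. For cytotoxic granule genes, camera gave adjusted p = 0.00871, and adjusted p = 0.496 with an estimated correlation. Of 22 trafficking receptor genes, 9 fell, 3 rose and 10 were not called (9 and 3 adjusted over the list alone), with Ccr1 at -1.96 ± 0.12 and Itga4 at -1.93 ± 0.13. For trafficking receptors, camera gave adjusted p = 0.0147, and adjusted p = 0.289 with an estimated correlation. Markers of NK cells gave 4 lower and 5 not called of 9 (4 adjusted over the list alone), including Gzma and Eomes (-0.64 ± 0.10), and markers of CD8 and gamma-delta T cells 4 lower and 1 not called of 5 (4 adjusted over the list alone), including Trgv4 (-3.71 ± 0.33) and Cd8b1 (-1.35 ± 0.28). Both had adjusted p = 0.0198, and adjusted p = 0.496 with an estimated correlation. With the mean of all probe sets, inhibitory receptors and NK cell markers were not called (adjusted p = 0.0518 for both). Of the members named, Gzmk, Ccr1, Xaf1 and Trgv4 (5.03, 4.99, 5.05 and 4.69) had PBAB means below the filter threshold of 5.07. The Th1 lineage and chemokine lists missed the threshold (adjusted p = 0.0506 and 0.0504), and were called without a filter (0.0299 and 0.0297). The Th1 lineage list was also called without any 1 of Th1 HA 2, Th1 PBAB 1, Th9 HA 1, Th9 PBAB 2 or Th17 HA 2 (0.0324 to 0.0417), and the chemokine list without any 1 of Th1 HA 1, Th1 HA 2, Th1 PBAB 2, Th9 HA 1, Th9 PBAB 2, Th17 HA 1 or Th17 PBAB 2 (0.0129 to 0.0447).

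Of the lineage genes in the average, Irf4 (1.35 ± 0.21), Il5 (1.04 ± 0.14, from a mean of 4.41 in HA, below the filter threshold) and Il12rb2 (0.78 ± 0.18) were higher in PBAB. Il10, an anti-inflammatory cytokine, was lower (-2.65 ± 0.35), as were Ifng (-1.06 ± 0.28), Gata3 (adjusted p = 0.00744) and Eomes. Several averages of called genes joined lineages of opposite sign, where the opposite value was not called in the fit without a block. Il10 was at -5.97, -2.73 and 0.76 in Th1, Th9 and Th17 cultures (Th17 against Th1 adjusted p = 0.00297). In the same order Ifng was at 0.26, 0.49 and -3.94, Il12rb2 at -0.83, 2.45 and 0.70, Gata3 at -1.26, 0.60 and -2.35, Il5 at 0.10, 3.26 and -0.24, Il2ra at -0.09, 1.42 and 1.58, Btla at 0.98, 2.99 and -0.17, and Gzmk at -3.59, 0.26 and -0.21. Il21 was called at 0.66 ± 0.23 (adjusted p = 0.0471), a call lost without each of Th1 HA 1, Th1 HA 2, Th1 PBAB 1, Th9 HA 2, Th9 PBAB 1, Th17 HA 2, Th17 PBAB 1 and Th17 PBAB 2 (adjusted p = 0.0515 to 0.125), without a filter (0.0515) and after centring each array (0.0698). Il2ra, a chain of the IL-2 receptor, was at 0.97 ± 0.15 with the probe set used, at -1.18 with its other probe set and at -0.10 with their mean. Not called were Tbx21 (-0.08), Il9 (0.41), Spi1 (-0.01), Il4 (0.11), Il13 (0.47) and Il17a (0.41). With the replicate block, these genes were also called: Cd4 (0.48, adjusted p = 0.00113), Cd3e (-0.44, 0.00549), Il2 (-0.34, 0.00645), Foxp3 (-0.70, 0.0109), Csf2 (0.60, 0.0279) and Pdk1 (-0.37, 0.0286). With the block within each lineage, Il13 and Il17a were called too (adjusted p = 0.00716 and 0.0296, against 0.0877 and 0.0726 with the other block). Without a block, Cd4 was called after quantile normalization again (0.0248) and without Th1 HA 1 or Th17 HA 1, Csf2 without Th9 HA 2 or Th17 PBAB 1, Foxp3 without Th9 PBAB 1 or Th17 PBAB 1, Il13 without Th9 PBAB 2, Il17a without Th17 HA 1 and Pdk1 without Th17 HA 2. Their adjusted p was at most 0.0318, 0.049, 0.0202, 0.0221, 0.00822 and 0.00684.

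**Figure D1:**
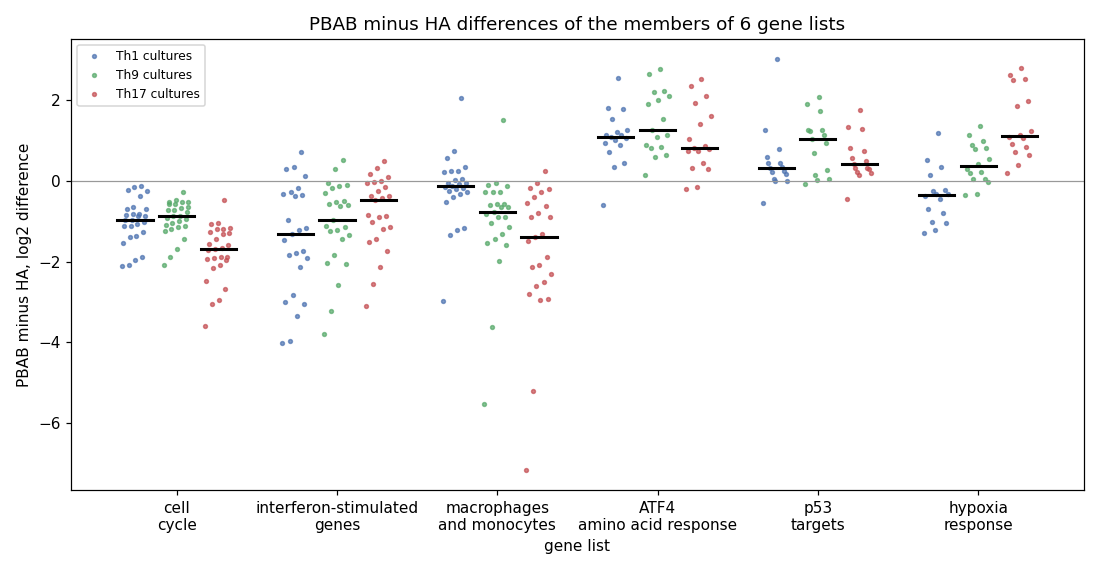
Each point is a gene, placed by its PBAB minus HA log2 difference (vertical axis) in Th1, Th9 or Th17 cultures, for 6 gene lists (horizontal axis), and black bars mark the list medians. The cell cycle medians lie at -0.95, -0.86 and -1.68, and the macrophage and monocyte medians at -0.13, -0.76 and -1.39.

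In Th1 cultures, 7 of 15 cytotoxic granule, 7 of 22 trafficking receptor and 7 of 15 Th1 lineage genes were lower in PBAB, while 2, 2 and 0 were higher. With an estimated correlation these lists had adjusted p = 0.546, 0.275 and 0.265. The largest decreases were in Gzma (-6.64 ± 0.91, 99.5-fold), the chemokine receptor Cxcr6 (-6.54 ± 0.64), Ifi209 (-6.47 ± 0.46), S100a6 (-6.10 ± 0.33) and Il10 (-5.97 ± 0.61). The largest increases were in Timp1 (6.53 ± 0.55, 92.4-fold), Cth (6.24 ± 0.53), Nupr1 (4.94 ± 0.38), the activation marker Cd83 (4.74 ± 0.48) and Nr4a3 (4.55 ± 0.19). The PBAB means of Ifi209 and Il10 (4.56 and 4.95) and the HA mean of Cth (4.29) lay below the filter threshold of 5.07. Ifng, the defining Th1 cytokine, was high in both (12.82 ± 0.54 SD in HA, 13.07 ± 0.20 SD in PBAB) and not called. Il2 rose by 1.96 ± 0.27, from a mean of 4.15 below that threshold. Tbx21, Il12rb2, Gata3 and Cd3e were not called at -1.32, -0.83, -1.26 and -0.54, and were called with the replicate block (adjusted p = 0.0288, 0.0377, 0.0185 and 0.0489), Cd3e not with the block within each lineage (0.0623). Without the block, Tbx21 was called without Th1 PBAB 1 (adjusted p = 0.0157) and Gata3 without Th9 HA 1 or Th9 HA 2 (0.00637), with array weights (0.0389) and with the 4 arrays fitted alone (0.0203). Irf4 was called at 1.48 ± 0.36, but not without Th1 HA 2, Th1 PBAB 1 or Th1 PBAB 2 (adjusted p = 0.0827 to 0.14) or with the 4 arrays fitted alone (0.0715).

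By list, 7 of 15 Th1 lineage genes fell in Th1 cultures and 8 were not called (9 fell and 1 rose adjusted over the list alone), among them Havcr2 (-3.16 ± 0.32) and Il18rap, a subunit of the IL-18 receptor (-2.75 ± 0.30). For Th1 lineage genes, camera gave adjusted p = 5.32e-05, and adjusted p = 0.265 with an estimated correlation. Of 15 cytotoxic granule genes, 7 fell, 2 rose and 6 were not called (8 and 3 adjusted over the list alone), Gzmk (-3.59 ± 0.26) and Gzme (-3.09 ± 0.27) first. For cytotoxic granule genes, camera gave adjusted p = 0.00644, and adjusted p = 0.546 with an estimated correlation. Trafficking receptor genes gave 7 lower, 2 higher and 13 not called of 22 (10 and 2 adjusted over the list alone), led by Cxcr6 and Ccr1 (-2.05 ± 0.20). For trafficking receptors, camera gave adjusted p = 0.00669, and adjusted p = 0.275 with an estimated correlation. Among interferon-stimulated genes, 16 fell, 1 rose and 8 were not called of 25 (16 and 1 adjusted over the list alone), with Isg20 at -4.02 ± 0.34 and Usp18 at -3.35 ± 0.28. For interferon-stimulated genes, camera gave adjusted p = 1.62e-08, and adjusted p = 0.265 with an estimated correlation. Of 27 cell cycle genes, 11 fell and 16 were not called (18 fell adjusted over the list alone), for example Rrm2 (-2.10 ± 0.29) and Birc5 (-1.96 ± 0.31). For cell cycle genes, camera gave adjusted p = 1.79e-08, and adjusted p = 0.546 with an estimated correlation. ATF4 genes gave 8 higher and 9 not called of 17 (11 adjusted over the list alone), with Asns, asparagine synthetase, at 2.54 ± 0.35 and Atf5 at 1.54 ± 0.23. For ATF4 genes, camera gave adjusted p = 2.18e-06, and adjusted p = 0.546 with an estimated correlation. Targets of p53 gave 3 higher and 12 not called of 15 (3 adjusted over the list alone), among them Perp (3.01 ± 0.16) and Bbc3 (1.26 ± 0.23). For p53 targets, camera gave adjusted p = 0.00674, and adjusted p = 0.546 with an estimated correlation. Of the members named, Havcr2, Gzmk and Gzme (5.04, 5.03 and 3.46) had PBAB means below the filter threshold of 5.07. Markers of macrophages gave 3 lower, 1 higher and 21 not called of 25 (4 and 2 adjusted over the list alone; adjusted p = 0.574).

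Other Th1 lists lost their call without single arrays. Early receptor response genes gave 5 higher, 1 lower and 17 not called of 23 (5 and 1 adjusted over the list alone), including Nr4a3 and Nr4a2 (3.09 ± 0.36). For early receptor response genes, camera gave adjusted p = 0.012, and adjusted p = 0.807 with an estimated correlation. That call was lost without Th1 HA 2 or Th1 PBAB 1 (0.296 and 0.0817). NK cell markers gave 3 lower and 6 not called of 9 (4 adjusted over the list alone), with Gzma and perforin, Prf1 (-1.93 ± 0.29). For NK cell markers, camera gave adjusted p = 0.00669, and adjusted p = 0.546 with an estimated correlation. The call of NK cell markers was lost without Th1 PBAB 1 (0.0562). Prf1 itself was not called with the mean of its probe sets (-0.66, adjusted p = 0.203). Of 15 genes of cholesterol synthesis, 3 fell and 12 were not called (3 adjusted over the list alone), Mvk (-1.18 ± 0.28) and Nsdhl (-0.80 ± 0.21) first. For cholesterol synthesis genes, camera gave adjusted p = 0.0286, and adjusted p = 0.807 with an estimated correlation. Of 15 genes matched for glycolysis, 2 fell, Ldha (-0.54 ± 0.14) and Slc16a3 (-1.46 ± 0.43), and 13 were not called (2 adjusted over the list alone). For glycolysis genes, camera gave adjusted p = 0.0317, and adjusted p = 0.83 with an estimated correlation. Pigq (-0.57), a gene of GPI anchor synthesis that entered this list through a synonym it shares with Gpi1, is not glycolytic, and without it 2 of 14 fell (3 adjusted over the list alone; adjusted p = 0.038, and adjusted p = 0.859 with an estimated correlation). The cholesterol call was lost without Th1 HA 1 or Th1 PBAB 2 (0.254 and 0.176) and with the mean of all probe sets (0.143), and the glycolysis call without Th1 HA 1 or Th1 PBAB 1 (0.146 and 0.0808). Mvk was not called without Th1 HA 1 or Th1 PBAB 2, nor Nsdhl and Ldha without any of the 4 Th1 arrays of these groups, nor Slc16a3 without Th1 HA 1, any Th1 PBAB, Th9 PBAB or Th17 PBAB array, with adjusted p up to 0.128, 0.179, 0.141 and 0.266. Ldha and Nsdhl were also not called with the 4 arrays fitted alone (0.109 and 0.054), nor Slc16a3 without a filter (0.0508). With the replicate block the CD8 and gamma-delta list was also called (adjusted p = 0.0437), but not with the block within each lineage (0.0515). In all, 2266 genes were called, 809 higher and 1457 lower in PBAB, and 4380 with the replicate block. The count was 1078 without Th1 HA 2, 1308 without Th1 PBAB 1 and 1124 without Th1 PBAB 2, and 35.7% of the calls were higher in PBAB against 47.1% after quantile normalization again.

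In Th9 cultures, 5 of 21 helper cytokine and 7 of 12 inhibitory receptor genes were higher in PBAB, and 9 of 25 macrophage markers were lower, while 1, 0 and 1 moved the other way. With an estimated correlation these lists had adjusted p = 0.474, 0.224 and 0.229. Il5 rose by 3.26 ± 0.24 (9.55-fold), from 5.28 ± 0.12 SD to 8.54 ± 0.06 SD. The largest increases were in Nupr1 (4.50 ± 0.38), Dapl1 (4.39 ± 0.21), Plek (4.35 ± 0.26), Cth (4.33 ± 0.53) and Nr4a3 (4.09 ± 0.19). The largest decreases were in Chil3, a chitinase-like protein of macrophages (-5.91 ± 0.24), Lyz1 (-5.52 ± 0.50), S100a6 (-5.30 ± 0.33), Fgl2 (-5.09 ± 0.37) and Tnfsf13b, which encodes BAFF (-5.08 ± 0.35). Il12rb2 rose by 2.45 ± 0.32 and Eomes fell by 1.56. The PBAB means of Chil3, Lyz1, S100a6 and Fgl2 (3.17, 3.93, 4.62 and 4.47) and the HA mean of Il12rb2 (4.58) lay below the filter threshold of 5.07. Il9, the cytokine that names the lineage, was 5.84 ± 0.64 SD in HA and 6.82 ± 2.11 SD in PBAB and was not called (adjusted p = 0.546), except without Th9 PBAB 2 (2.47, adjusted p = 0.0381).

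Other Th9 lineage genes were called with less support. Il13 (1.83 ± 0.36) was not called without Th9 HA 2 or Th9 PBAB 1, Il10 (-2.73 ± 0.61) and Csf2 (1.66 ± 0.40) without Th9 HA 1 or Th9 PBAB 1, and Il4 (0.72 ± 0.18) and Irf4 (1.59 ± 0.37) without Th9 HA 2, Th9 PBAB 1 or Th9 PBAB 2, with adjusted p up to 0.0656, 0.096, 0.136, 0.148 and 0.12. Tbx21 (1.51 ± 0.43, adjusted p = 0.0398) was not called without Th9 HA 1, Th9 HA 2, Th9 PBAB 1, Th17 PBAB 1 or Th17 PBAB 2 (up to 0.252) or with array weights (0.0589), nor Il4 with the 4 arrays fitted alone (0.0928). Il21 (0.99) and Cd4 (0.65) were called with the replicate block (adjusted p = 0.00294 and 0.0101). Gata3 was at 0.60 with all arrays and at 1.37 without Th9 HA 1.

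Of 21 helper cytokine genes in Th9 cultures, 5 rose, 1 fell and 15 were not called (5 and 1 adjusted over the list alone), with Il5 and Il13 first. For helper cytokines, camera gave adjusted p = 0.031, and adjusted p = 0.474 with an estimated correlation. This call was lost with the replicate block (adjusted p = 0.0615), though not with the block within each lineage (0.0392), and without Th9 HA 2 or Th9 PBAB 1 (0.0783 and 0.183). Inhibitory receptors gave 7 higher and 5 not called of 12 (7 higher and 1 lower adjusted over the list alone), Btla (2.99 ± 0.24) and Tox (2.04 ± 0.29) first. For inhibitory receptors, camera gave adjusted p = 0.000556, and adjusted p = 0.224 with an estimated correlation. ATF4 genes gave 9 higher and 8 not called of 17 (12 adjusted over the list alone), with Atf5 at 2.22 ± 0.23 and Ddit3 at 2.64 ± 0.30. For ATF4 genes, camera gave adjusted p = 8.55e-09, and adjusted p = 0.311 with an estimated correlation. Targets of p53 gave 9 higher and 6 not called of 15 (10 adjusted over the list alone), with Perp at 1.74 ± 0.16 and Bbc3 at 2.08 ± 0.23. For p53 targets, camera gave adjusted p = 8.1e-07, and adjusted p = 0.224 with an estimated correlation. Early receptor response genes gave 8 higher, 1 lower and 14 not called of 23 (11 and 1 adjusted over the list alone), Nr4a3 higher and the costimulatory receptor Icos lower (-2.64 ± 0.26). For early receptor response genes, camera gave adjusted p = 8e-05, and adjusted p = 0.474 with an estimated correlation.

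Cell cycle genes gave 10 lower and 17 not called of 27 in Th9 cultures (17 adjusted over the list alone), including Rrm2 (-2.07 ± 0.29) and Birc5 (-1.70 ± 0.31), the latter not called without Th9 HA 2 (adjusted p = 0.0517). For cell cycle genes, camera gave adjusted p = 2.02e-09, and adjusted p = 0.474 with an estimated correlation. Interferon-stimulated genes gave 12 lower and 13 not called of 25 (15 lower and 1 higher adjusted over the list alone), Ddx58 (-2.05 ± 0.22) and Xaf1 (-3.80 ± 0.45) first. For interferon-stimulated genes, camera gave adjusted p = 3.82e-08, and adjusted p = 0.224 with an estimated correlation. Macrophage markers gave 9 lower, 1 higher and 15 not called of 25 (14 and 1 adjusted over the list alone), with Lyz1 and Lyz2 (-3.62 ± 0.40). For macrophage markers, camera gave adjusted p = 3.82e-08, and adjusted p = 0.229 with an estimated correlation. The CD8 and gamma-delta markers gave 1 lower, Trgv4 (-4.75 ± 0.57), and 4 not called of 5 (2 adjusted over the list alone). For CD8 and gamma-delta markers, camera gave adjusted p = 0.014, and adjusted p = 0.474 with an estimated correlation. The call of CD8 and gamma-delta markers was lost without Th9 HA 2 or Th9 PBAB 1 (0.101 and 0.0848). Cd160 of this list was at -1.42 and called with the replicate block (adjusted p = 0.000549), with the mean of its probe sets (0.0497) and without Th17 HA 1 or Th17 HA 2 (0.0295). Genes of the unfolded protein response gave 4 lower and 8 not called of 12 (4 adjusted over the list alone), Sdf2l1 (-1.24 ± 0.20) and Creld2 (-1.01 ± 0.25) first. For unfolded protein response genes, camera gave adjusted p = 0.0314, and adjusted p = 0.809 with an estimated correlation. The call of unfolded protein response genes was lost without Th9 HA 1 or Th9 PBAB 2 (0.236 and 0.137). Of the members named, Xaf1, Lyz2 and Trgv4 (4.95, 4.99 and 4.94) had PBAB means below the filter threshold of 5.07. The Th2 lineage list missed the threshold (0.0609), and was called without a filter (0.0408), without members abundant in APC alone (0.0281) and without Th1 HA 1, Th1 HA 2, Th9 HA 1 or Th9 PBAB 2 (at most 0.0388). Creld2 was not called without Th9 HA 1, Th9 PBAB 1 or Th9 PBAB 2 (up to 0.128). In all, 2126 genes were called, 1146 higher and 980 lower in PBAB, 4056 with the replicate block, 1279 with the 4 arrays fitted alone, and 1056, 1080 and 1213 without Th9 HA 2, Th9 PBAB 1 and Th9 PBAB 2.

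In Th17 cultures, Il17a and 8 of 16 hypoxia genes were higher in PBAB, and Ifng, Il2, 24 of 27 cell cycle genes and 15 of 25 macrophage markers were lower. With an estimated correlation the 3 lists had adjusted p = 0.363, 0.306 and 0.306. Il17a, the defining Th17 cytokine, rose by 1.64 ± 0.30 (3.11-fold), while Ifng fell by 3.94 (SE 0.48), Il2 by 3.04 (SE 0.27) and Gata3 by 2.35 (SE 0.40). The largest increases were in Hspa1b (5.83 ± 0.27), Hspa1a (4.90 ± 0.35), S1pr3 (4.07 ± 0.54), Lbp (4.07 ± 0.37) and Map3k20 (3.95 ± 0.22). The largest decreases were in Lyz1 (-7.15 ± 0.50), Mndal (-5.35 ± 0.61), Lyz2 (-5.21 ± 0.40), the chemokine gene Ccl6 (-4.77 ± 0.52) and Ms4a4b (-4.50 ± 0.58). The PBAB means of Ifng, Il2, Lyz1, Mndal, Ccl6 and Ms4a4b (3.72, 4.27, 4.51, 3.25, 4.33 and 4.84) and the HA means of Hspa1b and Hspa1a (4.54 and 3.32) lay below the filter threshold of 5.07. Foxp3, the regulatory T cell factor, was called at -1.59 ± 0.43, but not without Th17 HA 1, Th17 HA 2 or Th17 PBAB 2 (adjusted p = 0.075 to 0.219). Irf4 (0.98), Il4 (-0.52) and Il21 (0.62) were called with the replicate block (adjusted p = 0.0102, 0.0295 and 0.0291), Il21 not with the block within each lineage (0.0526). Without the block, Irf4 was called without Th1 HA 1 or Th1 HA 2 (0.0218), with the mean of its probe sets (2.17, 0.00188), after quantile normalization again (1.13, 0.0407) and with the 4 arrays fitted alone (0.0295). Il4 was called with the mean of its probe sets (0.0481) and after quantile normalization again (0.0456). Csf2 (0.82, not called) was at 1.43 without Th17 PBAB 1.

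Among the 27 cell cycle genes in Th17 cultures, 24 fell and 3 were not called (26 adjusted over the list alone), Rrm2 (-3.04 ± 0.29) and Tk1 (-3.59 ± 0.39) first. For cell cycle genes, camera gave adjusted p = 2.49e-17, and adjusted p = 0.306 with an estimated correlation. Macrophage markers gave 15 lower and 10 not called of 25 (18 adjusted over the list alone), Cybb, a subunit of the phagocyte oxidase (-2.92 ± 0.20), and Lyz1 first. For macrophage markers, camera gave adjusted p = 1.17e-11, and adjusted p = 0.306 with an estimated correlation. Chemokine genes gave 4 lower and 9 not called of 13 (8 adjusted over the list alone), with Ccl9 at -3.74 ± 0.27 and Ccl3 at -2.97 ± 0.40. For chemokine genes, camera gave adjusted p = 2.44e-05, and adjusted p = 0.306 with an estimated correlation. Interferon-stimulated genes gave 11 lower and 14 not called of 25 (11 lower and 1 higher adjusted over the list alone), with Ifit2 at -2.14 ± 0.27 and Xaf1 at -3.11 ± 0.45. For interferon-stimulated genes, camera gave adjusted p = 0.000718, and adjusted p = 0.363 with an estimated correlation. Hypoxia genes gave 8 higher and 8 not called of 16 (10 adjusted over the list alone), Ero1a (2.50 ± 0.28) and Pfkfb4 (1.23 ± 0.18) first. For hypoxia genes, camera gave adjusted p = 7.75e-08, and adjusted p = 0.363 with an estimated correlation. ATF4 genes gave 8 higher and 9 not called of 17 (9 adjusted over the list alone), with Ddit3 at 2.36 ± 0.30 and Atf5 at 1.60 ± 0.23. For ATF4 genes, camera gave adjusted p = 8.61e-06, and adjusted p = 0.363 with an estimated correlation. Of 15 p53 targets, 5 rose and 10 were not called (5 adjusted over the list alone), Cdkn1a (1.77 ± 0.30) and Bbc3 (1.28 ± 0.23) first. For p53 targets, camera gave adjusted p = 0.000328, and adjusted p = 0.306 with an estimated correlation. Regulatory T cell genes gave 7 higher, 3 lower and 5 not called of 15 (7 and 3 adjusted over the list alone), the folate receptor family gene Izumo1r higher (1.82 ± 0.23) and the integrin gene Itgae lower (-3.65 ± 0.32). For regulatory T cell genes, camera gave adjusted p = 0.0253, and adjusted p = 0.306 with an estimated correlation. That call was lost with the mean of all probe sets (0.0808).

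Cholesterol synthesis genes in Th17 cultures gave 3 higher and 12 not called of 15 (5 higher and 1 lower adjusted over the list alone), Sc5d (0.97 ± 0.16) and Fdft1 (1.37 ± 0.28) first. For cholesterol synthesis genes, camera gave adjusted p = 0.00775, and adjusted p = 0.624 with an estimated correlation. The glycolysis list gave 3 higher and 12 not called of 15 matched genes (4 adjusted over the list alone), including Pfkp (1.03 ± 0.25) and Pfkfb3 (1.25 ± 0.33). For glycolysis genes, camera gave adjusted p = 0.0386, and adjusted p = 0.773 with an estimated correlation. Without Pigq (-0.82), which is not glycolytic, 3 of 14 rose (adjusted p = 0.0198, and adjusted p = 0.737 with an estimated correlation). The call of glycolysis genes was lost with the replicate block (adjusted p = 0.0685) and without Th17 HA 2 or Th17 PBAB 2 (0.594 and 0.0998). Early receptor response genes gave 5 higher and 18 not called of 23 (5 adjusted over the list alone), with Nr4a2 at 3.10 ± 0.36 and Nr4a3 at 1.47 ± 0.19. For early receptor response genes, camera gave adjusted p = 0.0158, and adjusted p = 0.711 with an estimated correlation. The call of early receptor response genes was lost without Th17 HA 2 or Th17 PBAB 1 (0.156 and 0.0601) and with the mean of all probe sets (0.0972). Cytotoxic granule genes gave 5 lower and 10 not called of 15 (5 adjusted over the list alone), Serpinb9 (-2.37 ± 0.23) and granzyme B, Gzmb (-3.37 ± 0.81), first. For cytotoxic granule genes, camera gave adjusted p = 0.0386, and adjusted p = 0.649 with an estimated correlation. The call of cytotoxic granule genes was lost without Th17 HA 2 or Th17 PBAB 1 (0.098 and 0.12) and with the mean of all probe sets (0.0808). MHC class II genes gave 2 lower, H2-Ob (-2.28 ± 0.18) and H2-Aa (-1.53 ± 0.30), and 7 not called of 9 (2 adjusted over the list alone). For MHC class II genes, camera gave adjusted p = 0.0386, and adjusted p = 0.37 with an estimated correlation. The call of MHC class II genes was lost without Th17 HA 2, Th17 PBAB 1 or Th17 PBAB 2 (0.0506 to 0.179) and without members abundant in APC alone (0.142). CD8 and gamma-delta markers gave 1 lower, Trgv4 (-4.16 ± 0.57), and 4 not called of 5 (4 lower adjusted over the list alone). For CD8 and gamma-delta markers, camera gave adjusted p = 0.0232, and adjusted p = 0.597 with an estimated correlation. The call of CD8 and gamma-delta markers was lost without Th17 HA 2 or Th17 PBAB 1 (0.098 and 0.0601). NK cell markers gave 3 lower and 6 not called of 9 (4 adjusted over the list alone) and missed the threshold at adjusted p = 0.0502. This list was called with the replicate block (adjusted p = 0.0394), without members abundant in APC alone (0.0301), and without any 1 of Th1 PBAB 1, Th1 PBAB 2, the Th9 arrays or Th17 PBAB 2 (at most 0.0488). Cd160 was at -1.47 (adjusted p = 0.0502), and was called with the block (0.00038) and without Th9 HA 1, Th9 HA 2 or Th17 HA 1 (at most 0.0452), with a stricter filter (0.0476) and without the arrays of APC alone (0.0484).

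The PBAB means of Serpinb9, Ccl9, Ccl3, Ifit2, Xaf1, Cybb, H2-Ob and Trgv4 (4.62, 4.98, 4.30, 4.78, 4.70, 4.33, 4.79 and 4.84) lay below the filter threshold of 5.07. Single genes of these Th17 lists also depended on 1 array. Fdft1 was not called without Th17 HA 1 or Th17 PBAB 2, Gzmb without Th17 HA 2 or Th17 PBAB 1, H2-Aa without Th17 HA 2, Pfkfb3 without Th17 HA 2 or Th17 PBAB 2, and Pfkp without Th17 HA 2, Th17 PBAB 1 or Th17 PBAB 2, with adjusted p up to 0.0736, 0.146, 0.0664, 0.193 and 0.148. With the 4 arrays fitted alone, Gzmb, Pfkfb3 and Pfkp were not called (adjusted p = 0.0793, 0.0668 and 0.0613). In all, 2648 genes were called in Th17 cultures, 1032 higher and 1616 lower in PBAB, and 4709 with the replicate block. The count was 1214 without Th17 HA 2, 1557 without Th17 PBAB 1 and 1392 without Th17 PBAB 2.

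**Figure D2:**
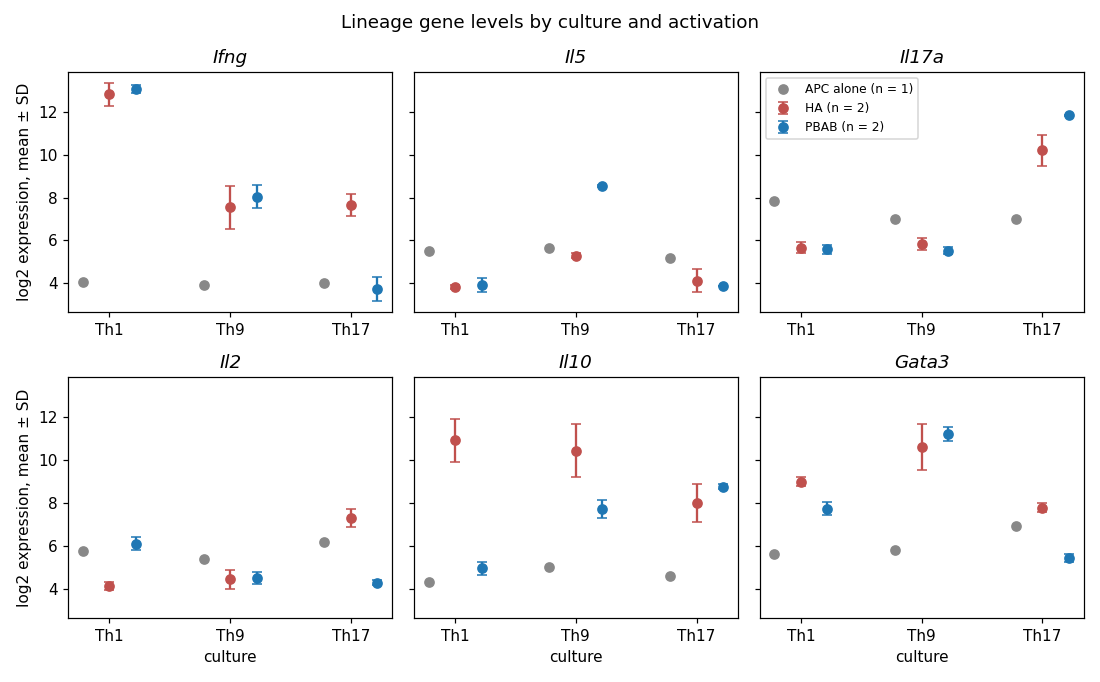
Mean log2 expression ± SD (vertical axis) of 6 genes in each culture (horizontal axis), with 1 array per point for APC alone and 2 for HA and PBAB. Ifng is at 12.82 and 13.07 in Th1 cultures under HA and PBAB, and at 7.66 and 3.72 in Th17 cultures.

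The activation difference depended on the lineage for 649 genes by the interaction test. Il2 was higher in PBAB in Th1 cultures (1.96), at 0.05 in Th9 and lower in Th17 (-3.04; interaction adjusted p = 0.000639). Chil3 was lower in Th9 cultures (-5.91) and at -0.04 and -0.36 in Th1 and Th17 (6.4e-05). Il5 was higher in PBAB in Th9 cultures, at 0.10 and -0.24 in the others (0.00121), and Ifng was lower in Th17 cultures, at 0.26 and 0.49 in the others (0.0081). Chil3 and Il5 in Th1 and Th17 and Il2 in Th9 cultures lay below the filter threshold under both activations. A lack of response there cannot be read. Between Th17 and Th1 cultures, macrophage markers differed in 12 of 25 members, all more negative in Th17 (camera adjusted p = 4.44e-12). Hypoxia genes were more positive in Th17 (3 of 16 called, 4.44e-12), as were cholesterol synthesis (2 of 15, 1.41e-06) and the glycolysis list (0 of 15, 1.29e-05). Without Pigq the glycolysis list had 0 of 14 called (4.62e-06). With an estimated correlation, adjusted p was 0.45 for glycolysis (0.479 without Pigq) and 0.326 for each of the others. Pairwise, 212 genes differed between Th9 and Th1, 547 between Th17 and Th1 and 265 between Th17 and Th9, and 739, 1828 and 1476 with the replicate block, which gave 2316 for the interaction. In Th17 against Th9, 35.5% were more positive in Th17, against 47.1% after quantile normalization again.

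These interaction counts moved with single arrays. The count of 649 was 326 and 332 without Th1 PBAB 1 and 2, 408 without Th9 PBAB 1, 309 without Th17 HA 2, and 361 and 360 without Th17 PBAB 1 and 2. For Th9 against Th1 it was 100 and 102 without Th1 PBAB 1 and 2, 136 without Th9 HA 2, and 138 and 100 without Th9 PBAB 1 and 2. For Th17 against Th1 it was 319 and 357 without Th1 HA 1 and 2, 224 and 214 without Th1 PBAB 1 and 2, 209 without Th17 HA 2, and 311 and 230 without Th17 PBAB 1 and 2. For Th17 against Th9 it was 118 and 141 without Th9 HA 1 and 2, 78 without Th9 PBAB 1, 64 without Th17 HA 2, and 75 and 143 without Th17 PBAB 1 and 2. Calls overlapped between lineages, with 485 genes higher in PBAB in both Th1 and Th9 cultures where independent lists would share 59.8, 366 in Th1 and Th17 (53.9) and 493 in Th9 and Th17 (76.3). Higher in HA were 605 (92.1), 660 (151.9) and 578 (102.2), and in all 3 lineages 277 genes were higher in PBAB, 421 higher in HA and 15 mixed.

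Under HA, the cultures differed in their lineage genes. Relative to Th1, Th9 cultures had higher Il4 (3.41 ± 0.18) and Il5 (1.46 ± 0.24) and lower Ifng (-5.27 ± 0.48), Tbx21, the Th1 master factor (-4.02 ± 0.43), Csf2 (-3.38 ± 0.40) and Il12rb2 (-3.25 ± 0.32). The largest differences were Chil3 (6.08 ± 0.24), Akr1c18 (5.67 ± 0.33) and Itgae (5.32 ± 0.32) upward and Serpinb5 (-5.44 ± 0.30), Ifng and Anxa1 (-5.18 ± 0.31) downward. Th17 relative to Th1 cultures had higher Il17a (4.53 ± 0.30), Il9 (4.63 ± 0.80), Foxp3 (3.68 ± 0.43), Il2 (3.16 ± 0.27) and Il21 (2.85 ± 0.39) and lower Ifng (-5.16 ± 0.48) and Tbx21 (-5.00 ± 0.43), with Aqp3 (4.91 ± 0.32) and Lyz1 (4.90 ± 0.50) upward and Gzmd (-5.65 ± 0.89), Ffar2 (-5.52 ± 0.17) and Anxa1 (-5.47 ± 0.31) downward. Th17 relative to Th9 cultures had higher Serpinb1a (5.47 ± 0.44), Il17a (4.35 ± 0.30), the chemokine receptor Ccr6 (4.13 ± 0.30) and Il21 (3.78 ± 0.39) and lower Chil3 (-5.79 ± 0.24), Epas1 (-5.71 ± 0.31), Trat1 (-4.86 ± 0.24), Gata3 (-2.83 ± 0.40), Il4 (-2.66 ± 0.18) and Eomes (-1.61 ± 0.18). Below the filter threshold of 5.07 under HA lay the means of Chil3, Il4, Il5, Foxp3 and Il2 (3.01, 4.51, 3.83, 4.69 and 4.15) in Th1, of Serpinb5 and Il12rb2 (4.42 and 4.58) in Th9 and of Gzmd, Chil3 and Il5 (2.96, 3.29 and 4.12) in Th17 cultures. Th1 lineage genes were lower in Th17 than in Th1 cultures (12 of 15 called, 3 not). For Th1 lineage genes, camera gave adjusted p = 5.33e-17, and adjusted p = 0.0143 with an estimated correlation. Th17 lineage genes were higher (10 of 14 called, 4 not). For Th17 lineage genes, camera gave adjusted p = 2.03e-15, and adjusted p = 0.0545 with an estimated correlation. Macrophage markers were higher in Th17 than in Th1 cultures under HA (14 of 25 called, 11 not). For macrophage markers, camera gave adjusted p = 4.24e-16, and adjusted p = 0.0545 with an estimated correlation.

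Some calls between lineages under HA rested on single arrays. Between Th9 and Th1 cultures, Eomes (0.79), Il13 (1.55) and Gata3 (1.62) were not called without either Th1 HA or Th1 PBAB array. This also held without Th9 HA 2 for Eomes, without Th9 HA 1 or 2 for Il13, and for Gata3 without any other activated array but Th9 HA 2, with adjusted p up to 0.228, 0.173 and 0.209. Between Th17 and Th1, Eomes (-0.82) was not called without any of the 4 arrays, Il4 (0.75) without Th1 HA 2, Th17 HA 1 or Th17 HA 2, Il10 (-2.92) without Th1 HA 1 or Th17 HA 2 and Il9 without Th17 HA 2 (up to 0.139, 0.206, 0.142 and 0.0578). Between Th17 and Th9, Il9 (3.86) and Foxp3 (2.25) were not called without Th9 HA 2 or Th17 HA 2, nor Il9 without Th9 HA 1 or Foxp3 without Th17 HA 1, nor Il5 (-1.17) without Th9 HA 1, Th9 HA 2 or Th17 HA 1 (up to 0.165, 0.108 and 0.12). Il13 (-1.52) and Il10 (-2.44, adjusted p = 0.0491) each lost the call without 9 arrays, up to 0.246 and 0.322. Those arrays were all activated ones but Th9 PBAB 1, Th9 PBAB 2 and Th17 HA 2 for Il13, and all but Th1 HA 1, Th1 HA 2 and Th9 HA 2 for Il10. The replicate block added calls for Il21 and Foxp3 in Th9 against Th1 (adjusted p = 0.00875 and 0.0162), Irf4 and Gata3 in Th17 against Th1 (0.0197 and 0.036) and Irf4 in Th17 against Th9 (0.0132). Without the block, Foxp3 was called in the first without Th9 PBAB 1 or 2 (0.0316), Gata3 in the second without Th9 HA 1 or 2 (0.0122), and Irf4 without Th1 HA 1 in the second (0.013) and without Th1 HA 1 or 2 in the third (0.0318). With the compared arrays fitted alone, Eomes and Gata3 in Th9 against Th1 (adjusted p = 0.191 and 0.215), Eomes, Il4 and Il10 in Th17 against Th1 (0.0683, 0.129 and 0.0625) and Il13 and Il10 in Th17 against Th9 (0.0622 and 0.117) were not called, while Foxp3 in the first and Gata3 in the second were (0.0391 and 0.0388). Centring each array ended the calls of Gata3 in the first and of Il13 and Il10 in the third (0.0687, 0.0548 and 0.0626), and array weights those of Il13 and Il10 (0.0646 and 0.0666). In all, 827, 1069 and 739 genes were called, 1863, 2373 and 1831 with the block, and 365, 556 and 310 with the compared arrays fitted alone. Without Th1 HA 2, Th9 HA 1 and Th9 HA 2 the first count was 510, 508 and 474, without Th1 HA 1, Th1 HA 2 and Th17 HA 2 the second was 709, 695 and 591, and without Th9 HA 1, Th9 HA 2, Th17 HA 1 and Th17 HA 2 the third was 374, 390, 372 and 364.

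Under PBAB, Th9 relative to Th1 cultures had higher Il5 (4.61 ± 0.24), Maf (4.58 ± 0.27), Il4 (4.00 ± 0.18), Gata3 (3.48 ± 0.40) and Il13 (3.34 ± 0.36) and lower Ms4a4b (-5.34 ± 0.58), Il18r1 (-5.33 ± 0.20) and Ifng (-5.05 ± 0.48). Th17 relative to Th1 cultures had higher Il17a (6.26 ± 0.30), Maf (5.74 ± 0.27), Lbp (5.01 ± 0.37), Il9 (4.87 ± 0.80), Il10 (3.81 ± 0.61) and Il21 (3.09 ± 0.39) and lower Ifng (-9.35 ± 0.48), Serpinb6b (-6.38 ± 0.36), Ccl3 (-6.22 ± 0.40), Tbx21 (-4.14 ± 0.43) and Il2 (-1.84 ± 0.27). Th17 relative to Th9 cultures had higher Serpinb1a (6.34 ± 0.44), Il17a (6.31 ± 0.30), Lbp (5.09 ± 0.37) and Il21 (3.41 ± 0.39) and lower Gzmb (-5.80 ± 0.81), Gata3 (-5.78 ± 0.40), Nkg7 (-5.33 ± 0.66), Il5 (-4.66 ± 0.24), Ifng (-4.31 ± 0.48), Il4 (-3.90 ± 0.18), Il13 (-3.82 ± 0.36) and Tbx21 (-2.95 ± 0.43). Below the filter threshold of 5.07 under PBAB lay the means of Il5, Il4, Il10 and Foxp3 (3.93, 4.63, 4.95 and 4.55) in Th1, of Ms4a4b, Il18r1 and Il2 (4.98, 4.97 and 4.49) and Serpinb1a (4.62) in Th9 and of Ifng, Ccl3, Tbx21, Il2, Il4 and Il5 (3.72, 4.30, 5.06, 4.27, 4.73 and 3.88) in Th17 cultures. Th17 lineage genes were higher in Th17 than in Th1 cultures (10 of 14 called, 4 not). Th1 lineage genes gave 8 lower, 1 higher and 6 not called of 15. For these lists camera gave adjusted p = 1.46e-15 and 2.5e-06, and adjusted p = 0.0654 with an estimated correlation for each.

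Calls under PBAB that rested on single arrays included Gzma (4.36), Il10 (2.77) and Il2 (-1.62) in Th9 against Th1. Gzma was not called without Th1 PBAB 1, Th9 PBAB 2 or any HA array, nor Il10 without any PBAB array. Il2 was not called without Th1 PBAB 2 or Th9 PBAB 1. Il9 (1.74, not called) was at 3.23 without Th9 PBAB 2. In Th17 against Th1, Eomes (-0.76) was not called without any of the 4 arrays, Csf2 (-1.63) and Foxp3 (2.23) without Th1 PBAB 1, Th1 PBAB 2 or Th17 PBAB 1, Gata3 (-2.30) without Th1 PBAB 1 or Th17 PBAB 1, and Il12rb2 (-1.43) without Th1 PBAB 1, Th17 PBAB 1 or Th17 PBAB 2 (up to 0.214, 0.231, 0.0887, 0.0628 and 0.17). In Th17 against Th9, Il12rb2 (-1.47) was not called without Th9 PBAB 2, Th17 PBAB 1 or Th17 PBAB 2, and Il9 (3.13, adjusted p = 0.0464) without 9 arrays, namely all Th1 and Th9 HA arrays, both Th1 and both Th17 PBAB arrays and Th9 PBAB 2 (up to 0.152 and 0.273). Foxp3 (1.03, not called) was at 1.72 without Th9 PBAB 1. With the compared arrays fitted alone, Gzma in Th9 against Th1 and Il9 in Th17 against Th9 were not called (adjusted p = 0.186 and 0.0728) and Il10 in Th17 against Th9 (1.04) was (0.0462). Centring each array ended the calls of Il10 in Th9 against Th1 and of Il9 in Th17 against Th9 (0.0563 and 0.0526), and an intensity trend did as well (0.0568 and 0.0564). In all, 334 genes were called for Th9 against Th1, 1083 for Th17 against Th1 and 987 for Th17 against Th9, and 861, 2642 and 2351 with the replicate block. The first count was 123 and 134 without Th1 PBAB 1 and 2, 154 and 143 without Th9 PBAB 1 and 2, and 162 with the 4 arrays fitted alone. The second was 455 and 515 without Th1 PBAB 1 and 2 and 608 and 494 without Th17 PBAB 1 and 2, and the third 467 and 502 without Th9 PBAB 1 and 2 and 509 and 458 without Th17 PBAB 1 and 2.

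Genes abundant in APC alone, defined as at least 1 log2 unit above the PBAB arrays with no floor in level, made up 26.7% of the 15498 genes tested. The arrays of APC alone had a narrower range and a higher median (mean 5.91 against 5.49 in PBAB), so weakly expressed genes can meet this definition. Among genes called higher in HA they made up 7.62% in Th1 (111 of 1457), 12.6% in Th9 (123 of 980) and 9.22% in Th17 cultures (149 of 1616). Among genes called higher in PBAB they made up 6.06%, 2.18% and 1.65%. The PBAB arrays both define these genes and form the contrast, which by itself lowers the share among genes higher in PBAB. The difference between the 2 shares is therefore partly fixed in advance. For genes higher in HA the share was 9.78% without Th1 PBAB 2 in Th1, 17.9% without Th9 HA 1 and 16.6% without Th9 PBAB 2 in Th9, and 12.2% without Th17 HA 2 or Th17 PBAB 1 in Th17 cultures. For genes higher in PBAB it was 4.04% without Th1 HA 1 in Th1 cultures.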

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

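The 3 tests of splenocyte RNA and the 2 tests of Ifng were chosen only after the results they measure had been seen. The activation difference was tested for a dependence on the lineage, and results that passed are given here. The interaction test called 649 genes, and pairwise 212 genes differed between Th9 and Th1, 547 between Th17 and Th1 and 265 between Th17 and Th9. Of 98 genes named in the activation contrasts, 45 had an interaction adjusted p under 0.05.

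Among these 45 genes, the difference was largest in size in Th1 cultures for Cxcr6 (0.0159), Gzme (0.00404), Gzmk (0.00119), Havcr2 (0.00782), Isg20 (0.0074), Il10 (0.0065), Nr4a3 (0.000882), Perp (0.00172), Prf1 (0.0211), S100a6 (0.00384), Timp1 (0.0178) and Usp18 (0.00453). It was largest in Th9 cultures for Btla (0.00245), Ccl9 (0.00153), Chil3 (6.4e-05), Dapl1 (0.000215), Eomes (0.0186), Fgl2 (0.00702), Icos (0.0291), Il12rb2 (0.00886), Il4 (0.0454), Il5 (0.00121), Itgae (0.00287), Plek (0.00307) and Tnfsf13b (0.00624). It was largest in Th17 cultures for Ccl3 (0.00163), Cybb (0.00132), Ero1a (0.0138), Gata3 (0.0372), H2-Ob (0.00171), Hspa1a (0.0484), Hspa1b (0.0163), Ifng (0.0081), Il17a (0.0451), Il2 (0.000639), Il2ra (0.0395), Itga4 (0.00484), Lbp (0.00289), Lyz1 (0.0205), Lyz2 (0.00925), Map3k20 (0.00651), Pfkfb4 (0.0174), S1pr3 (0.0205), Sc5d (0.0118) and Serpinb9 (0.00289). The values in parentheses are interaction adjusted p from limma, and which pairs of lineages differed was tested gene by gene, as for Ifng (Th17 against Th1 adjusted p = 0.00891, Th9 against Th1 0.955) and Il17a (0.0572 and 0.92). The interaction does not test which lineage was largest, and for many genes the 2 largest differences were not called apart. Examples are Itgae, Il2ra and Lyz1 between Th17 and Th9 (adjusted p = 0.983, 0.919 and 0.325). Others are Fgl2 and Nr4a3 between Th9 and Th1 (0.8 and 0.623) and Gata3 between Th17 and Th1 (0.413). The value of Il2ra is that of the probe set used, and its other probe set moved the opposite way in the average.

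Macrophage and monocyte genes were higher in HA than in PBAB, and the design adds irradiated splenocytes to HA cultures. Each HA and PBAB group held 1 array of each replicate number, so a difference between numbers is balanced and cannot make this shift. The median shift was -0.61 within the number where it was smaller and -0.87 within the other. RNA of added splenocytes with the profile of the APC-alone arrays, whose bioB control lay at 13.94 against 10.17 in HA, is 1 possible source. The 17 called members implied a median share of 3.81% of such RNA, inside the quartiles of 1.19 to 4.71% over the 20 genes furthest above PBAB in APC alone, 7 of which are also called members. Without these 7 the quartiles were 1.11 to 6.39%, but the members' shares spread from 0.894 to 33.8%, and by culture their median lay inside the quartiles in Th17 (9.27%, against 2.5 to 11.8%) and above the upper quartiles in Th1 and Th9 (0.591 and 4.92%, against 0.391 and 4.27%). In Th17 cultures 2 of the 17 members implied over 100%, up to 110%, which no share can give, and splenocytes changed by coculture and expression by the T cells themselves stay open and were not tested. Macrophage genes such as Csf1r and Chil3 are also among the 20 reference genes, so the agreement is partly fixed in advance. Changed splenocytes could give it too, so it does not tell these sources apart.

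Cell cycle genes were lower in PBAB, with median shifts of -0.94 and -1.39 within the replicate numbers, which are balanced between the activations by design. The median shift was -1.19 with each array centred and -1.06 after quantile normalization again, which argues against scaling as the whole cause. A first test of splenocyte RNA counted members lower in APC alone than in PBAB. It gave 25 of 27, or 23 after quantile normalization again, and was read as undecided. With that seen, it was replaced by a count of called members higher in HA than in both, a level that mixing these profiles cannot give. All 26 were (25 after quantile normalization again), which restates the calls and that all 27 lay lower in APC alone than in HA. Adding APC-alone RNA would lower the 25 first counted, so it is not a likely cause. A difference in proliferation and the differences in the actin and 18S controls stay open and were not tested.

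Interferon-stimulated genes were lower in PBAB, by medians of -1.15 and -1.18 within the replicate numbers. Of 18 called members, 16 lay higher in HA than in both APC alone and PBAB (17 after quantile normalization again), which argues against RNA with the profile of APC alone. In Th1 and Th9 cultures, where no antibody against IFN-gamma is listed, Ifng differed by 0.26 and 0.49 (neither called), on average by 0.37 (95% interval -0.38 to 1.12), while the median of the list in that average was -1.16, which argues against a fall of Ifng transcript as large as that of the list. In Th17 cultures, which held such an antibody at 20 µg/ml, the shift was less negative than in Th1 by a median of 0.46 (unadjusted camera p = 0.00027, and 0.0968 with an estimated correlation), which says nothing about Ifng as a source. A smaller fall of Ifng, interferon from other cells and the activation itself stay open.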

How the results depend on the processing

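Leaving out the 3 arrays of APC alone, the block with an estimated correlation, the lists without Pigq, the 75th percentile floor and the margin after quantile normalization again were chosen only after the data were seen, and the cause was not tested for any change below unless fewer arrays or a stricter definition made it. Counting each named gene in each contrast and alternative once, 7948 results kept their side of the threshold, 205 lost a call, 91 gained one and 1 reversed, and for gene lists these numbers were 2592, 130, 46 and 0. Among those that kept their side, no called value changed sign, while 82 values of genes and 118 of lists that were not called did. The reversed result was Il2ra in the average, at -0.10 with the mean of all probe sets. Without the 3 arrays of APC alone the activation counts were 2314, 2159, 2686 and 4788 (Th1, Th9, Th17 and average), and 655 for the interaction. With the preset correlation, camera called 11, 10, 14 and 12 of 35 lists in Th1, Th9, Th17 and the average. With an estimated correlation it called 0 in each, where 3, 5, 5 and 5 had an unadjusted p under 0.05, and 0 with the replicate block as well. Without Pigq it called the same 11, 10, 14 and 12 lists. Other lists not called with all arrays were called without a single array. In Th1 cultures these were STAT5 targets and hypoxia (adjusted p = 0.00389 and 0.0431, both without Th1 HA 2). In Th9 cultures they were STAT5 targets (0.0369 and 0.0381), hypoxia (0.00352), regulatory T cells (0.0387), stroma (0.0212) and trafficking receptors (0.033 and 0.0443), and in Th17 cultures neutrophils (0.045) and trafficking receptors (0.0166 and 0.0424, and 0.0434 without a filter). Without members abundant in APC alone, inhibitory receptors were called in Th1 and Th17 cultures (0.00471 and 0.0301).

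With the replicate block the counts were 4380, 4056 and 4709 in Th1, Th9 and Th17 cultures, 2316 for the interaction, and 739, 1828 and 1476 for Th9 against Th1, Th17 against Th1 and Th17 against Th9. In the same order of lineages they were 1863, 2373 and 1831 under HA and 861, 2642 and 2351 under PBAB. With the block within each lineage they were 4196, 3880, 4568, 2035, 634, 1591, 1362, 1659, 2243, 1703, 721, 2469 and 2206 in that order. Beyond the calls given beside the results and the lists above, neither form of the block changed another call of a named gene or list. With a 2-fold minimum the counts were 1184, 1143 and 1356 in the single lineages, 1009 in the average, and 683 and 634 for Th17 against Th1 and Th9 under PBAB. With only the compared arrays in the fit, which leaves fewer degrees of freedom, they were 1279 in Th9 cultures, 135 for Th9 against Th1, 144 for Th17 against Th9, 365, 556 and 310 between lineages under HA and 162 for Th9 minus Th1 under PBAB.

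Leaving out 1 array at a time gave 1078 to 2213 genes in Th1, 1056 to 2061 in Th9 and 1214 to 2654 in Th17 cultures, and 309 to 578 for the interaction. Pairwise it gave 100 to 204, 209 to 546 and 64 to 248, under HA 474 to 795, 591 to 1065 and 364 to 719, and under PBAB 123 to 310, 455 to 1043 and 458 to 946. The share of genes abundant in APC alone ranged from 7.07 to 9.78% (Th1), 11.5 to 17.9% (Th9) and 9.41 to 12.2% (Th17) among genes higher in HA, and from 4.04 to 7.07% among genes higher in PBAB in Th1 cultures.

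That share followed its definition, and the share over all genes tested was not computed for the definitions below. Given as genes higher in HA, then in PBAB, for Th1, Th9 and Th17 cultures in turn, a margin of 0.5 gave 13.9% and 9.52%, 20.8% and 4.45%, and 14.6% and 4.94%. A margin of 2 gave 1.72% and 0.865%, 4.9% and 0.0873%, and 4.46% and 0%. The margin after quantile normalization again gave 13.3% and 11.6%, 19% and 7.68%, and 15.8% and 8.04%. A floor at the 75th percentile gave 2.81% and 3.83% in Th1, 5.51% for genes higher in HA in Th9, and 5.2% and 0.775% in Th17 cultures. Against the PBAB arrays of the other 2 lineages, 2.81% of the genes higher in PBAB in Th17 cultures were abundant in APC alone. The number of arrays limits all of these counts, and signals near background limit the differences of weakly expressed genes, since 78 of the 250 called differences of named genes had a group mean below the filter threshold of 5.07. Among them were Ifng, at 3.72 in Th17 PBAB arrays, and Il2, at 4.15 in Th1 HA arrays.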

Other observations

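In this part the splits of the arrays and the contrast of Il9 were planned before the results were seen, and the test between replicate numbers was chosen afterwards. Il9 was at 9.71 ± 0.99 (SD, n = 2) in Th17 HA and 9.95 ± 0.81 in Th17 PBAB cultures, and at 5.84 ± 0.64 and 6.82 ± 2.11 in the Th9 cultures named after it. Under HA the Th17 minus Th9 difference of Il9 was 3.86 ± 0.80, called by limma (adjusted p = 0.0219), but not without Th9 HA 1, Th9 HA 2 or Th17 HA 2 (adjusted p = 0.0634 to 0.165).

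Replicate number itself separated the arrays. Over the 12 activated arrays, 4547 genes were called between numbers 2 and 1, of which 2001 were higher and 2546 lower in number 2. The bioB hybridisation control averaged 9.53 and 10.81 in HA arrays with numbers 1 and 2, and 9.68 and 10.99 in PBAB arrays. The 18S signal averaged 10.68 and 9.49 in HA, and 11.24 and 10.16 in PBAB.

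In the averaged activation contrast, 1 of 32 splits that part the same pairs, the real one, gave 4735 genes and the highest other gave 1157. The other splits set HA and PBAB arrays in the same group or reverse a whole lineage. The activation difference then enters the spread or partly cancels, so this count does not exclude chance. For HA against APC alone, 1 of 84 splits of the 9 arrays, the real one, gave 13346 genes and the highest other gave 0. Every other split mixes both kinds of array, so the difference between them enters the spread, and this count adds no support.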
